A study of Caenorhabditis elegans with 6 samples.

How the data were processed

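Total RNA from staged L4 hermaphrodites of strain N2 was hybridised to 6 Affymetrix arrays, 3 from larvae raised on plain medium and 3 from larvae raised with 1 mg/mL sodium perchlorate, both for 48 hours at 20 °C. Per the labels' protocols, RNA was extracted with Trizol and a glass-bead step, column-purified, treated with DNase, and amplified into biotin-labelled cDNA. The group of each array and its replicate number were taken from the sample titles. The growth and treatment notes of the control samples repeat the perchlorate exposure, while their titles, descriptions and treatment entries name them as controls; the titles were followed.

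The deposited values are log2 probe set values, which the authors made with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects the background, normalises quantiles across arrays and summarises probes into probe sets. Versions of these tools and a genome build were not given in the sources used here, so no coordinates are printed. The deposited table was used as it stands, with no further normalisation and no filter on dim probe sets. It held 29317 rows, of which 25546 had 1 gene symbol in the platform annotation, 646 had several and 3125 had none. The 26192 with at least 1 gene were tested, and no gene was named from a probe set with several. Symbols, gene biotypes and chromosomes came from the platform annotation and the RefSeq gene table of assembly WBcel235. By biotype, 18847 rows were protein-coding, 5982 non-coding RNA and 612 pseudogenes. The 3125 rows with no gene were left out of the tests; 388 of them had an unadjusted limma p under 0.05 in a fit over all rows, 262 higher and 126 lower, and 0 passed adjusted.

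Perchlorate was compared with control in limma 3.58.1 under R 4.3.3, with lmFit and eBayes without trend, a two-sided test, Benjamini-Hochberg adjustment over all tested rows and a threshold of 0.05. The fit had 4 residual degrees of freedom and 3.12 prior degrees of freedom. The median within-group SD was 0.147 in controls and 0.193 with perchlorate, and the median SE of a log2 difference was 0.153. The number of arrays limits the precision. The median log2 difference over all tested rows was 0.03.

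Gene lists were tested with camera of limma at a preset correlation of 0.01, on 1 value per gene, the brightest probe set with 1 symbol, over 25478 genes. Lists with at least 5 measured members were tested, with a minimum of 3 for the vitellogenins, and adjusted over 58 lists. Of 59 lists fixed, 1 had 4 measured members and was not tested, and 63 listed symbols were not measured. The lists covered stress and detoxification pathways, ion transport, immunity, metabolism, moulting, germline, stage and tissue markers. Some genes stand in more than 1 list. Within each list limma p-values were also adjusted over the list alone. X-linked and autosomal genes were compared with Fisher's exact test, two-sided.

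Lists, tests and the rule for named genes were chosen before the data were examined. The rule named genes past the adjusted threshold whose groups did not overlap, up to 12 in each direction, and, where fewer than 5 passed, the 5 with the smallest p in that direction. It also named, in each list that passed, up to 4 members past the threshold in the direction of the list or, where none passed, the 2 with the largest differences, and the 2 largest in the metal, osmotic, peroxidase, vitellogenin and adult-onset cuticle lists. Other list members given as examples were chosen after their values were seen, most of them because they passed adjusted over the list alone.

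The procedure was tested on simulated data of 26192 rows, of which 200 were changed, with noise drawn from each row's moderated variance. It recovered 0% of rows changed by 0.5 on the log2 scale, 62.7% of those changed by 1 and 97% of those changed by 2, with 8 false calls. Moderated variances differ between rows less than unmoderated ones, so recovery on the real arrays may be lower. Of 55 higher and 244 lower real rows at least 2-fold apart at an unadjusted limma p under 0.05, 2 were called. The slope of the estimate on the true change was 0.99. Of 20 simulated sets without any change 0 had a list that passed. Genes were simulated independently of each other, whereas the estimated correlation on the real arrays was, for instance, 0.322 in the moulting list. The simulation therefore cannot show how often lists pass without a change when their members vary together.

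Alternatives tried were the replicate number as a block, each array left out in turn, quantile normalisation applied again, centring each array on its median, 2 filters on dim rows at the 25th percentile and the median, all rows including those with no gene, a trended and robust prior, array weights, 1 probe set per gene, limma treat against a 1.2-fold change, and for the lists camera with an estimated correlation, camera on ranks, fry, and the mean of all probe sets of a gene. Counts of list members without perchlorate replicate 1, list tests without it at an estimated correlation, and the chromosome test at an unadjusted p were added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.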

Results

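Gene expression was measured on 6 Affymetrix arrays in wild-type N2 hermaphrodites of the nematode Caenorhabditis elegans. Synchronised larvae were raised from L1 to L4 for 48 hours at 20 °C, either on plain medium (control, n = 3 arrays) or with 1 mg/mL sodium perchlorate in the agar and in the bacterial food (perchlorate, n = 3 arrays). Perchlorate is an oxidising anion known in vertebrates for blocking iodide uptake by the thyroid. Median log2 values of the tested probe sets were 5.85, 5.87 and 5.83 on the control arrays and 5.85, 5.81 and 5.89 on the perchlorate arrays. Correlations between arrays lay between 0.9909 and 0.9928 within the control group, between 0.9836 and 0.9873 within the perchlorate group, and between 0.9793 and 0.988 across groups. The first principal component held 38.9% of the variance, and perchlorate replicate 1 stood apart on it with a score of 47.7, beside 12.2 and 13.1 for the other perchlorate arrays and -27.2, -25.9 and -20 for the controls. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these samples, which could be technical.

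The comparison addressed which transcripts differ between larvae raised with and without perchlorate. Expression of clec-17, a C-type lectin gene, fell from a log2 level of 5.6 ± 0.0841 in controls to 4.12 ± 0.111 with perchlorate (SD, n = 3 each), which is 0.359 of the control level. The log2 difference was -1.48 (SE 0.115, limma adjusted p = 0.0456). The perchlorate level of clec-17 lay near the lower quartile of the perchlorate arrays (4.09, 4 and 4.08). Its control level lay below the array medians, so the size of the fall is uncertain. A probe set assigned to 2 genes, and so left unnamed, fell from 8.29 ± 0.237 to 5.88 ± 0.151 (SD, n = 3 each), a log2 difference of -2.40 (SE 0.156, limma adjusted p = 0.0261). These were the 2 of 26192 probe sets that passed at a limma adjusted p under 0.05; both were lower, 0 were higher, and both changed at least 2-fold. The clec-17 call was lost when any 1 array was left out, with limma adjusted p between 0.0918 and 0.355. No probe set passed without perchlorate replicate 1, where the smallest limma adjusted p was 0.102, and the smallest on leaving out any of the 6 arrays lay between 0.0516 and 0.276.

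The individual genes next in rank did not pass in this fit. Among those higher with perchlorate, the C-type lectin gene clec-52 was at 6.52 ± 0.311 in controls and 8.12 ± 0.0860 with perchlorate (SD, n = 3 each), a log2 difference of 1.6 (SE 0.170, limma adjusted p = 0.0939). A second lectin gene, clec-227, differed by 1.14 (SE 0.142, limma adjusted p = 0.12). The protein-coding genes K10C2.12 and B0205.12 differed by 1.02 and 0.86, and the non-coding RNA F41H10.36 by 1.28, with limma adjusted p between 0.0939 and 0.12. Among those lower, sysm-1, an immune-response gene of the p38 pathway set, was at 9.51 ± 0.0239 in controls and 8.17 ± 0.242 with perchlorate (SD, n = 3 each), a log2 difference of -1.34 (SE 0.144, limma adjusted p = 0.0939). The tetraspanin gene tsp-2 differed by -1.33, pcp-4, which encodes a prolyl carboxypeptidase-like protein, by -1.19, and C23H3.9 by -1.1, each at a limma adjusted p of 0.0939. For each of these genes all 3 perchlorate values lay on one side of all 3 control values. Each passed with a trended and robust prior (limma adjusted p between 0.0139 and 0.037), and none passed on leaving out any 1 array.

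Many probe sets showed smaller differences. At an unadjusted limma p under 0.05 there were 4291 probe sets, 16.38% of those tested, where 1310 would be expected by chance; 2217 were higher and 2074 lower with perchlorate. Of those that also differed at least 2-fold, 55 were higher and 244 lower, so that 81.6% were lower. The 3 perchlorate and 3 control values did not overlap for 6296 probe sets, 24% of those tested, beside the 10% that chance gives for 3 against 3. Of these, 3364 were higher and 2932 lower. This share was 33.2% without perchlorate replicate 1, beside 20% by chance. Adjusted over all genes, limma called 9 probe sets at 0.1 and 1892 at 0.2.

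**Figure D1:**
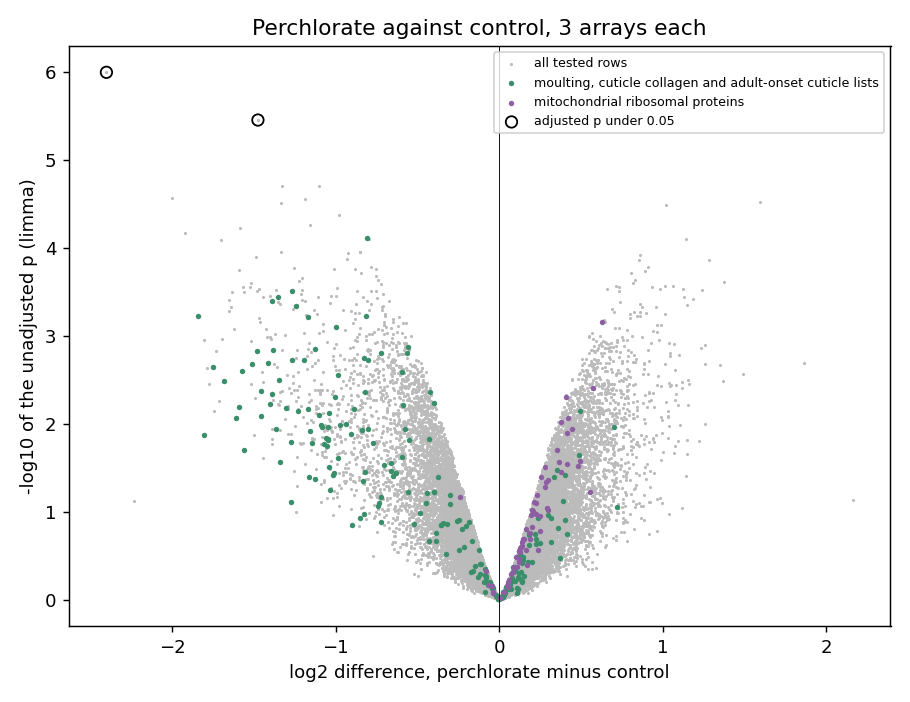
The log2 difference between perchlorate and control (horizontal axis) is plotted against the -log10 unadjusted limma p (vertical axis) for each of the 26192 tested probe sets, 3 arrays per group. Genes of the moulting, cuticle collagen and adult-onset cuticle lists (green) lie mostly left of 0, mitochondrial ribosomal protein genes (purple) mostly right of 0, and circles mark the 2 probe sets at an adjusted p under 0.05.

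Gene lists were fixed before the data were examined. Of 58 lists tested with camera at a preset correlation, 20 passed, 15 of them lower with perchlorate and 5 higher. With an estimated correlation 0 lists passed: the smallest camera adjusted p was 0.413, and 6 lists had an unadjusted p under 0.05. Correlation among members does not by itself account for this loss. The pan-neuronal and fatty acid synthesis lists lost their calls with estimated correlations of -0.001 and 0.004, below the preset 0.01. With an estimated correlation camera takes its p from the residual degrees of freedom of the fit, 4 here. With a preset correlation it takes its p from degrees of freedom set by the number of genes. With so few arrays a list therefore needs a larger difference to pass, also at a correlation near 0. The directional fry test, which does not compare a list with other genes, also passed 0 lists (smallest adjusted p = 0.0502), while its mixed form, which asks whether members change in either direction, passed 52. In each of the 20 lists 0 members were called adjusted over all genes, in either direction, so that the counts of members below are those adjusted over the list alone. Such counts were also taken without perchlorate replicate 1, but not without any other array. A loss of members there cannot be told apart from the lower precision of fewer arrays.

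**Figure D2:**
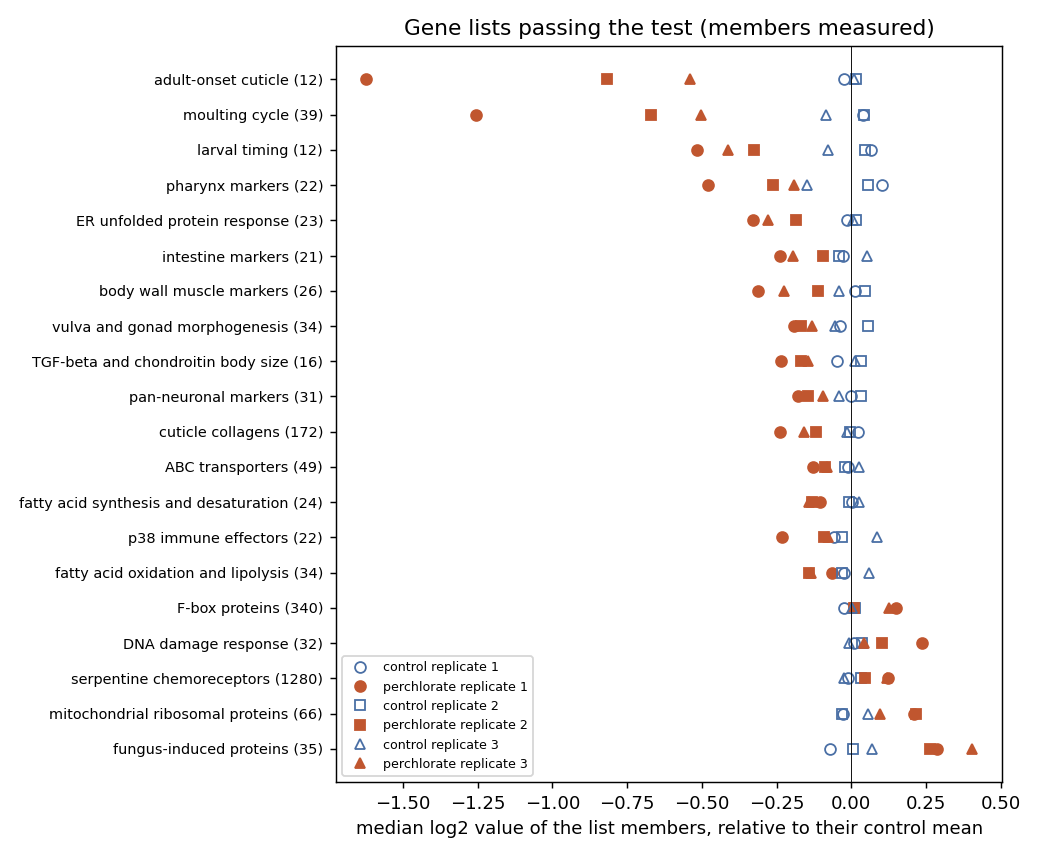
Median log2 value of the members of each of the 20 passing lists on each array, relative to the control mean of each gene (horizontal axis, log2), with open symbols for the 3 control arrays and filled symbols for the 3 perchlorate arrays, and the number of measured members in brackets. Perchlorate replicate 1 lies lowest for the adult-onset cuticle (-1.623) and moulting (-1.255) lists.

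Genes of the moulting cycle formed the list with the smallest camera p. Of its 39 members, which build, shed and replace the cuticle at each larval stage, 38 lay below 0, with a median log2 difference of -0.82. The list fell (camera adjusted p = 1.44e-20, and adjusted p = 0.413 with an estimated correlation). Of these genes 27 were lower, 0 were higher and 12 did not pass adjusted over the list alone. The largest differences were in mlt-11, which encodes a protease inhibitor-like protein needed for moulting, and in wrt-4, a hedgehog-related gene. For mlt-11 the log2 level was 8.91 ± 0.468 in controls and 7.07 ± 0.510 with perchlorate, and for wrt-4 it was 9.25 ± 0.166 and 7.50 ± 0.824 (SD, n = 3 each). The log2 differences were -1.84 (SE 0.315) and -1.75 (SE 0.377), with limma adjusted p of 0.125 and 0.148 over all genes and 0.00587 and 0.00792 adjusted over the list alone. Other members lower adjusted over the list alone included noah-1 (-1.40) and noah-2 (-1.23), genes of the apical extracellular matrix, and nas-36 (-0.97), an astacin protease gene. The medians of the list on the perchlorate arrays were -1.255 in replicate 1, -0.669 in replicate 2 and -0.503 in replicate 3, against 0.039, 0.042 and -0.083 in controls. Without perchlorate replicate 1 the median was -0.58 and 28 members were lower adjusted over the list alone.

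The adult-onset cuticle list and the cuticle collagens fell as well. Among 12 measured genes of the adult-onset cuticle list the median log2 difference was -1.06 (camera adjusted p = 0.00124, and adjusted p = 0.413 with an estimated correlation), with 6 lower, 0 higher and 6 not passing adjusted over the list alone. Its largest differences were in the collagen genes col-38 and col-63. For col-38 the level was 10.71 ± 0.103 in controls and 8.90 ± 1.25 with perchlorate, and for col-63 it was 9.93 ± 0.0738 and 8.24 ± 0.864 (SD, n = 3 each). The log2 differences were -1.81 (SE 0.551) and -1.69 (SE 0.388), at limma adjusted p of 0.0318 and 0.0193 adjusted over the list alone. The wide perchlorate SDs reflect values of 7.46 for col-38 and 7.25 for col-63 in replicate 1, and without that array the col-38 difference was -1.085. Over all genes the limma adjusted p of col-38 was 0.194 with all arrays and 0.122 without replicate 1, and 7 members were lower adjusted over the list alone without it. The members did not move together: bli-1 and bli-2, which encode collagens of the struts in the adult cuticle, differed by -1.35 and -1.07, whereas the adult collagen genes col-19 and col-7 differed by 0.21 and 0.01. The list median was -1.623 in perchlorate replicate 1, -0.816 in replicate 2 and -0.539 in replicate 3, and it was -0.59 without replicate 1.

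Across 172 measured cuticle collagen genes the median log2 difference was -0.14 and the mean -0.36 (camera adjusted p = 1.31e-06, and adjusted p = 0.493 with an estimated correlation). There were 14 lower and 0 higher adjusted over the list alone, and the remaining collagen genes did not pass. On leaving out perchlorate replicate 1, 38 were lower. Those lower included sqt-1 (-1.51), sqt-2 (-1.57), sqt-3 (-1.48) and dpy-3 (-1.39), collagen genes known from mutants with altered body shape. The differences of the 172 genes ran from -1.81 to 0.72, with 108 below 0 and 64 above. The median was -0.33 over the collagen genes above the 25th percentile of brightness and -0.54 over those above the median.

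Genes of larval timing fell as a list, with a median log2 difference of -0.41 over 12 measured members (camera adjusted p = 1.72e-05, and adjusted p = 0.413 with an estimated correlation). There were 5 lower, 0 higher and 7 not passing adjusted over the list alone. Leading the list were lin-42, the period homologue whose transcript cycles with each moult, and the collagen gene col-17. The level of lin-42 was 7.72 ± 0.253 in controls and 6.47 ± 0.324 with perchlorate (SD, n = 3 each), a log2 difference of -1.24 (SE 0.203, limma adjusted p = 0.122 over all genes and 0.00541 adjusted over the list alone). For col-17 it was 11 ± 0.0295 and 9.91 ± 0.689 (SD, n = 3 each), with -1.09 for all arrays and -0.71 without perchlorate replicate 1. The heterochronic genes lin-14, lin-41 and lin-28 differed by -0.24, -0.21 and 0.13.

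The body-size list of TGF-beta signalling and chondroitin genes fell, with a median log2 difference of -0.15 over 16 members (camera adjusted p = 0.00161, and adjusted p = 0.413 with an estimated correlation), and 5 were lower, 0 higher and 11 not passing adjusted over the list alone. The largest differences were -1.0 (SE 0.342) in lon-8, which encodes a secreted protein of the epidermis, and -0.94 (SE 0.270) in the collagen gene lon-3. Only the latter of these passed adjusted over the list alone (limma adjusted p = 0.0322, beside 0.0591 for lon-8). These differences were -0.58 and -0.61 without perchlorate replicate 1.

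The list of the unfolded protein response of the endoplasmic reticulum, which holds chaperone genes and regulators, fell with a median log2 difference of -0.25 over 23 members and 21 of them below 0 (camera adjusted p = 1.28e-06, and adjusted p = 0.413 with an estimated correlation). Of the 23 genes 7 were lower, 0 higher and 16 not passing adjusted over the list alone; without perchlorate replicate 1, 0 were. The 7 included pdi-6, a protein disulfide isomerase gene, at 11.32 ± 0.0592 in controls and 10.87 ± 0.119 with perchlorate (SD, n = 3 each), a log2 difference of -0.45 (SE 0.114, limma adjusted p = 0.0481 adjusted over the list alone). The others included pdi-2 (-0.45), hsp-3 (-0.37), a homologue of the chaperone BiP, and xbp-1 (-0.41), the transcription factor gene of the response. The largest difference, in abu-1, was -0.83 (SE 0.392), and it did not pass adjusted over the list alone (limma adjusted p = 0.12). It was -0.33 without perchlorate replicate 1.

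Coelomocyte and epidermis markers did not pass, with a median log2 difference of -0.09 over 15 members, 8 of them below 0 (camera adjusted p = 0.111). In that list 3 genes were lower and 0 higher adjusted over the list alone, against 0 lower without perchlorate replicate 1. Body wall muscle markers fell, with a median log2 difference of -0.19 over 26 members (camera adjusted p = 1.72e-05, and adjusted p = 0.413 with an estimated correlation). Among them 4 were lower, 0 higher and 22 did not pass adjusted over the list alone, against 0 lower without perchlorate replicate 1. Of the giant sarcomere proteins, unc-89 differed by -0.69 (SE 0.184) and passed adjusted over the list alone (limma adjusted p = 0.046), and ttn-1 differed by -0.60 (SE 0.191) and did not (limma adjusted p = 0.061). Pan-neuronal markers fell with a median of -0.15 over 31 members (camera adjusted p = 0.00112, and adjusted p = 0.413 with an estimated correlation), and 0 members passed adjusted over the list alone. Its largest differences were -0.65 (SE 0.151) in unc-44, an ankyrin gene, and -0.54 (SE 0.137) in unc-13, a gene of synaptic vesicle priming. Intestine markers fell with a median of -0.21 over 21 members (camera adjusted p = 0.00161, and adjusted p = 0.413 with an estimated correlation), and this median was -0.10 without control replicate 3. In that list 1 intestine gene was lower, 0 were higher and 20 did not pass adjusted over the list alone: the cysteine protease gene cpr-6, which differed by -0.69 (SE 0.124, limma adjusted p = 0.0167), and which did not pass without perchlorate replicate 1.

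Pharynx markers fell with a median log2 difference of -0.31 over 22 members (camera adjusted p = 0.0134, and adjusted p = 0.682 with an estimated correlation), and 0 passed adjusted over the list alone. The largest differences were in abu-14 (-1.34, SE 0.399) and abu-11 (-1.12, SE 0.424), whose products resemble proteins of the pharyngeal cuticle. The level of abu-14 was 11.65, 11.68 and 11.35 on the control arrays and 9.21, 10.69 and 10.76 on the perchlorate arrays. Without perchlorate replicate 1 the list median was -0.14, the difference was -0.84 in abu-14 and -0.60 in abu-11, and 6 members were lower and 1 higher adjusted over the list alone. Genes of vulva and gonad morphogenesis fell with a median of -0.17 over 34 members, or -0.11 without perchlorate replicate 1 (camera adjusted p = 0.00203, and adjusted p = 0.413 with an estimated correlation). Adjusted over the list alone 1 was lower, 0 higher and 33 did not pass. That gene was cog-1, a homeobox gene of vulval and gonad development, at 7.97 ± 0.0415 in controls and 7.42 ± 0.0410 with perchlorate (SD, n = 3 each), and 0 passed without perchlorate replicate 1. The troponin C gene tnc-2, of the pharynx and vulva lists, differed by 0.53 (SE 0.139).

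**Figure D3:**
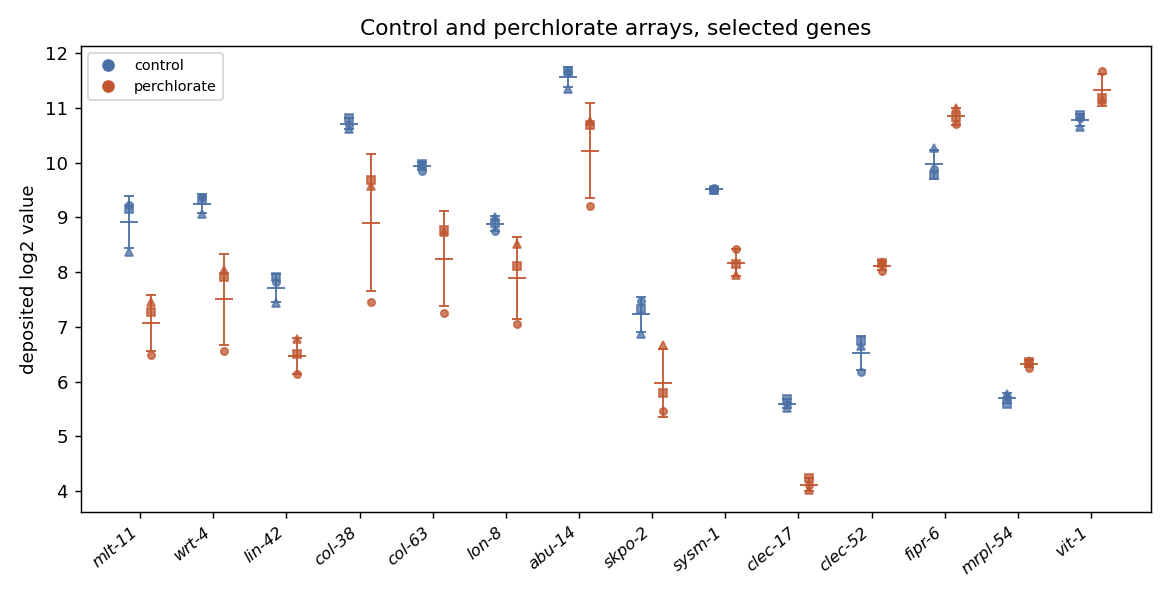
Deposited log2 values (vertical axis) of 14 named genes on the 3 control (blue) and 3 perchlorate (red) arrays, with circles, squares and triangles for replicates 1, 2 and 3, long ticks for the group mean and bars for the SD. Perchlorate replicate 1 is the lowest array for wrt-4, col-38, col-63, lon-8 and abu-14, whereas the 3 perchlorate values of clec-17 lie between 4.02 and 4.24.

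Of 66 measured mitochondrial ribosomal protein genes 60 lay above 0, with a median log2 difference of 0.19, which is 1.14 times the control level, and the list rose (camera adjusted p = 1.18e-06, and adjusted p = 0.493 with an estimated correlation). Adjusted over the list alone 1 was higher, 0 lower and 65 did not pass, and 0 passed without perchlorate replicate 1. The gene that passed, mrpl-54, was at 5.70 ± 0.0968 in controls and 6.33 ± 0.0671 with perchlorate (SD, n = 3 each), a log2 difference of 0.63 (SE 0.110, limma adjusted p = 0.0457 adjusted over the list alone). For mrpl-18 the difference was 0.57 (SE 0.137). The list median was 0.211, 0.217 and 0.095 on the perchlorate arrays. The 62 cytosolic ribosomal protein genes had a median of -0.01 (camera adjusted p = 0.447).

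The list of fungus-induced protein genes, most of them related genes with the stem fipr, rose with a median log2 difference of 0.29 over 35 members (camera adjusted p = 0.000356, and adjusted p = 0.413 with an estimated correlation). The name does not by itself mean that a member is induced by fungi. Adjusted over the list alone 6 were higher, 0 lower and 29 did not pass, and 3 were higher without perchlorate replicate 1. The median was 0.46 over the 18 members above the median brightness. Its leading members were fipr-6, at 9.97 ± 0.262 in controls and 10.84 ± 0.150 with perchlorate, and fipr-10, at 10.92 ± 0.231 and 11.61 ± 0.287 (SD, n = 3 each). The log2 differences were 0.87 (SE 0.163) and 0.69 (SE 0.187), at limma adjusted p of 0.0353 and 0.044 adjusted over the list alone. Members of this family have similar sequences, so their probe sets can share signal.

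Effectors of the p38 immune pathway fell as a list, with a median log2 difference of -0.06 and a mean of -0.20 over 22 members (camera adjusted p = 0.0161, and adjusted p = 0.493 with an estimated correlation). Of these effectors 6 were lower, 0 higher and 16 not passing adjusted over the list alone. They were led by sysm-1 (-1.34, limma adjusted p = 0.000677 adjusted over the list alone) and by cld-9 (-0.87, SE 0.214, limma adjusted p = 0.03 adjusted over the list alone). The call ended without perchlorate replicate 1, where the median was -0.02 (camera adjusted p = 0.0806) and 3 members were lower and 1 higher adjusted over the list alone, and without control replicate 3 (median -0.04, camera adjusted p = 0.173). Without control replicate 2 the median was -0.10, as it was without perchlorate replicate 2, and without perchlorate replicate 3 it was -0.09. It was -0.12 over rows above the 25th percentile of brightness and over those above the median, -0.03 with array weights, and the list did not pass over rows above the median or on ranks (camera adjusted p = 0.0537 and 0.0684).

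Lipid metabolism genes had small differences. Fatty acid synthesis and desaturation genes fell with a median log2 difference of -0.11 over 24 members (camera adjusted p = 0.0113, and adjusted p = 0.413 with an estimated correlation), and 0 passed adjusted over the list alone. The fatty acid synthase gene fasn-1 differed by -0.52 (SE 0.121) and sbp-1, the homologue of the lipogenic factor SREBP, by -0.36 (SE 0.132). The list did not pass without control replicate 3, on quantile normalising again or over rows above the median brightness (camera adjusted p = 0.066, 0.0569 and 0.0537). Fatty acid oxidation and lipolysis genes fell with a median of -0.05 and a mean of -0.11 over 34 members (camera adjusted p = 0.0365, and adjusted p = 0.464 with an estimated correlation). Adjusted over the list alone 1 was lower, the acyl-CoA dehydrogenase gene acdh-7 (-0.66, SE 0.130), 0 were higher and 33 did not pass; 0 passed without perchlorate replicate 1. The lipase gene lipl-4 differed by -0.67 (SE 0.169). This list did not pass without control replicate 3, perchlorate replicate 2 or perchlorate replicate 3 (camera adjusted p = 0.178, 0.0501 and 0.0938), and its median was -0.08 without control replicate 1, -0.12 without perchlorate replicate 1 and -0.12 without perchlorate replicate 3. The call also ended on quantile normalising again (median -0.03), above the 25th percentile of brightness, with array weights and on ranks (camera adjusted p = 0.106, 0.0786, 0.0647 and 0.07), and the median was -0.13 over rows above the median brightness.

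Of the remaining passing lists, each lost its call on leaving out at least 1 array, and none had a member that passed adjusted over the list alone. ABC transporter genes fell with a median log2 difference of -0.12 over 49 members (camera adjusted p = 0.0277, and adjusted p = 0.493 with an estimated correlation). In this list the pseudogene abt-6 differed by -0.84 (SE 0.290) and the P-glycoprotein gene pgp-5 by 0.76 (SE 0.221). The call was lost without control replicate 1, control replicate 3 or perchlorate replicate 1 (medians -0.12, -0.08 and -0.07, camera adjusted p = 0.0521, 0.103 and 0.22), on quantile normalising again and above the 25th percentile of brightness (0.0585 and 0.069), and the median was -0.07 with array weights. DNA damage response genes rose with a median of 0.11 over 32 members (camera adjusted p = 0.049, and adjusted p = 0.752 with an estimated correlation). The checkpoint gene hus-1 differed by 0.53 (SE 0.159) and the mismatch repair gene msh-2 by 0.42 (SE 0.166). That list did not pass without control replicate 1, 2 or 3 (camera adjusted p = 0.0553, 0.0765 and 0.103) nor without perchlorate replicate 1 or 2 (0.424 and 0.088), nor with arrays centred on their medians (0.0647) or with array weights (0.0719), and its median was 0.06 without perchlorate replicate 1.

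Serpentine chemoreceptor genes, a large family of putative odorant and taste receptors, rose with a median log2 difference of 0.11 over 1280 members (camera adjusted p = 0.00768, and adjusted p = 0.493 with an estimated correlation). Their median log2 level was 3.44, and 9 of the 1280 lay above the median of all tested probe sets. The median of these 9 was -0.10. The largest differences were in srbc-78 (0.92, SE 0.615), which rests on a value of 5.25 in perchlorate replicate 3 beside 3.01 and 2.68 in the others and which was 0.11 without that array, and in str-45 (-0.87, SE 0.163). The call was lost without perchlorate replicate 3 (camera adjusted p = 0.0725) and on quantile normalising again (median 0.05, camera adjusted p = 0.214). F-box protein genes, many of which are predicted adaptors of ubiquitin ligases, rose with a median of 0.10 over 340 members (camera adjusted p = 0.0293, and adjusted p = 0.682 with an estimated correlation). Here the pseudogene fbxa-21 differed by -1.03 (SE 0.167) and fbxc-32 by 0.77 (SE 0.150). The call was lost without control replicate 1, perchlorate replicate 1 or perchlorate replicate 3 (camera adjusted p = 0.0767, 0.119 and 0.138) and on quantile normalising again (0.14), and the median was 0.15 without perchlorate replicate 2 and 0.17 over the 61 members above the median brightness.

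Lists chosen for the exposure did not pass. Metal response genes had a median log2 difference of 0.01 and a mean of -0.02 over 16 members (camera adjusted p = 0.73), or a median of -0.04 without perchlorate replicate 1, with 0 members passing adjusted over the list alone. The zinc transporter gene cdf-2 differed by -0.48 (SE 0.224), or -0.26 without perchlorate replicate 2, and cdr-4, a cadmium-responsive gene, by -0.47 (SE 0.119). Osmotic response genes had a median of -0.10 over 23 members (camera adjusted p = 0.653), with 0 passing adjusted over the list alone. At an unadjusted limma p under 0.05, 7 of the 23 were higher and 5 lower, beside 16.38% of all tested probe sets. The groups did not overlap for 10 higher and 7 lower members, beside 24% of all. Members thus differed in both directions, which a median or a directional test cannot show. Without perchlorate replicate 1, 4 were higher and 4 lower at that unadjusted p. In this list osm-8, a mucin-like gene of the epidermis, differed by -0.87 (SE 0.194) and osr-1 by -0.70 (SE 0.290), or -0.34 without perchlorate replicate 1, while gpdh-1, the glycerol-producing enzyme gene induced by salt, differed by 0.49. Heme peroxidases and dual oxidases had a median of 0.01 and a mean of -0.16 over 11 members (camera adjusted p = 0.59), again with 0 passing adjusted over the list alone. The peroxidase gene skpo-2 was at 7.23 ± 0.319 in controls and 5.98 ± 0.621 with perchlorate (SD, n = 3 each), a log2 difference of -1.25 (SE 0.317, limma adjusted p = 0.159). For mlt-7, a peroxidase gene needed for moulting, the difference was -0.49 (SE 0.261), or -0.17 without perchlorate replicate 1. Oxidative stress and SKN-1 targets had a median of -0.03 and a mean of 0.06 over 33 members (camera adjusted p = 0.854), with 1 higher, the nitrilase gene nit-1 (0.96), and 1 lower, the catalase gene ctl-1 (-0.65), adjusted over the list alone. On leaving out perchlorate replicate 1 the median was 0.01, and 1 was higher and 0 lower. Solute and ion transport genes for sodium and anions had a median of -0.004 over 49 members (camera adjusted p = 0.736), with nhx-5 (-0.68) lower and best-3 (0.58) higher adjusted over the list alone, against 1 lower and 2 higher without perchlorate replicate 1.

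Families of detoxification enzymes did not pass as lists. Glutathione S-transferases had a median log2 difference of 0.15 over 48 members (camera adjusted p = 0.118), cytochrome P450s one of 0.09 over 74 (camera adjusted p = 0.692), short-chain dehydrogenases one of 0.10 over 34 (camera adjusted p = 0.321) and UDP-glucuronosyltransferases one of 0.08 over 67 (camera adjusted p = 0.103). Of the last family 5 were higher and 1 lower adjusted over the list alone, the higher ones being ugt-53 (0.99), ugt-26 (0.93), ugt-41 (0.92), ugt-63 (0.82) and ugt-40 (0.59). Without perchlorate replicate 1 this family passed (median 0.12, camera adjusted p = 0.0155, and adjusted p = 0.698 with an estimated correlation). Cytosolic heat shock genes had a median of -0.01 and a mean of 0.22 over 13 members (camera adjusted p = 0.142), and 4 small heat shock genes were higher adjusted over the list alone, hsp-16.41 (0.76), hsp-12.6 (0.75), hsp-12.3 (0.61) and hsp-16.2 (0.48). On leaving out perchlorate replicate 1, 0 were, and the median was 0.04.

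Germline and yolk genes, which mark progress towards adulthood, did not pass either. Spermatogenesis genes had a median log2 difference of 0.14 over 36 members (camera adjusted p = 0.0521), and passed without perchlorate replicate 1 (median 0.15, camera adjusted p = 0.0299, and adjusted p = 0.451 with an estimated correlation). Germline proliferation and meiosis genes had a median of 0.10 over 40 members (camera adjusted p = 0.111), or 0.05 without perchlorate replicate 1. Oogenesis and eggshell genes had one of 0.04 over 32 (camera adjusted p = 0.642), or -0.02 without that array. The 5 vitellogenins, yolk protein genes of the adult intestine, had a median of 0.30 (camera adjusted p = 0.158), and 0 passed adjusted over the list alone. The level of vit-1 was 10.77 ± 0.110 in controls and 11.33 ± 0.295 with perchlorate, and that of vit-5 was 11.89 ± 0.0487 and 12.23 ± 0.164 (SD, n = 3 each). The medians of the vitellogenins on the perchlorate arrays were 0.518 in replicate 1, 0.108 in replicate 2 and 0.201 in replicate 3, and the list median was 0.16 without replicate 1. Of 13 stable reference genes 11 were measured, with a median of 0.04 and a mean of -0.02 (camera adjusted p = 0.736).

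The distribution over chromosomes could not be judged from the called genes, since 0 of 1 called gene with a chromosome was X-linked (Fisher's exact test, two-sided p = 1). At an unadjusted limma p under 0.05, a threshold chosen after seeing the data, 512 of the lower genes were X-linked and 1512 autosomal. The X-linked share was 25.3%, against 18.8% among the other genes (odds ratio 1.46, Fisher's exact test, two-sided p = 5.76e-12). Of the higher genes 320 were X-linked and 1830 autosomal, a share of 14.9% against 19.7% (odds ratio 0.712, Fisher's exact test, two-sided p = 2.89e-08). Without control replicate 1 the latter odds ratio was 0.978 (exact p = 0.772), and without control replicate 2 it was 0.949 (exact p = 0.474). For the lower genes the odds ratio lay between 1.42 and 1.62 on leaving out any 1 array, each with an exact p under 0.05. Genes of one chromosome are not independent replicates, so these p-values describe the genes on these arrays.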

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

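Except for the chromosome test at an unadjusted p, the alternatives here were planned before the data were examined. The count of 2 probe sets called by limma was 0 in the fit with 1 probe set per gene, 0 on leaving out each array in turn (lowest 0, highest 0), 1 after quantile normalisation again, 1 with each array centred on its median, 1 over all rows and 1 with limma treat. It was 97 (26 higher, 71 lower) over rows above the median, and 328 (103 higher, 225 lower) with a trended and robust prior. It was 2 above the 25th percentile and 2 with array weights. The cause was not tested. At an unadjusted p under 0.05 the counts ran from 1349 with treat to 4746. The clec-17 difference lay between -1.535 and -1.425 in these fits. Against 20 lists, between 16 and 23 passed in the settings other than camera with an estimated correlation and fry, each with 0, and 17 to 19 on leaving out 1 array. Of the 20 themselves 15 to 20 passed in those settings, and 15 to 19 on leaving out 1 array. Across lists and settings, 286 results kept their direction and side of the threshold, 73 lost the call (20 each with an estimated correlation and with fry), and 1 turned: the chemoreceptor median was -0.0987 over the 9 members above the median brightness; 1280 members enter otherwise. Apart from those 2 tests 13 lists kept their call in all settings and 7 lost it in at least 1: chemoreceptors, F-box proteins, ABC transporters, p38 effectors, DNA damage response and both fatty acid lists. No named gene changed direction; 30 results gained and 12 lost a call, the latter all for clec-17. X-linked genes numbered 5 of 24 called higher and 15 of 65 called lower over rows above the median, against 0 and 0 in the fit over all tested rows. In the fit over all tested rows the smallest limma adjusted p was 0.0261, so a threshold of 0.01 left no gene for a chromosome test. The labels give both groups replicates 1 to 3. Residuals of same-numbered arrays correlated at 0.028, -0.018 and -0.006, so the numbers do not pair the arrays. With the replicate block 0 probe sets and 19 lists passed; DNA damage response lost its call (camera adjusted p = 0.105). Dim probe sets, such as those of chemoreceptors at a median level of 3.44, lie near the lower end of the scale, which limits what they can show.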

Other observations

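The hypotheses below were set against tests; those of brightness, of perchlorate replicate 1 and of mitochondrial ribosomal proteins were chosen after the results were seen, and those of stage, X linkage and other splits before.

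Families of genes that share a symbol stem were examined after the data were seen, 239 of them with at least 8 members; 44 passed camera at the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.588). The smallest p was that of 91 genes with the stem unc, named from mutants with uncoordinated movement, with a median log2 difference of -0.19 (camera adjusted p = 6.48e-08, and adjusted p = 0.588 with an estimated correlation). The families given next were picked by hand from those that passed. All 9 cadherin genes (cdh) lay below 0, with a median of -0.49 (camera adjusted p = 2.93e-06, and adjusted p = 0.588 with an estimated correlation), and the 24 patched-related genes (ptr) had a median of -0.33, or -0.21 without perchlorate replicate 1 (camera adjusted p = 2.26e-05, and adjusted p = 0.588 with an estimated correlation). The 14 bus genes, known from mutants with altered surface and bacterial attachment, had a median of -0.67, or -0.47 without perchlorate replicate 1, and the 14 abu genes one of -0.89, or -0.41 without it. Among the higher ones were the 58 transthyretin-related genes (ttr), with 44 above 0 and a median of 0.16 (camera adjusted p = 0.00531, and adjusted p = 0.789 with an estimated correlation), and the 11 rpb genes of RNA polymerase subunits, all above 0 with a median of 0.19 (camera adjusted p = 0.011, and adjusted p = 0.7 with an estimated correlation).

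Of 16 lysozyme genes ilys-2 (1.24) and lys-6 (1.04) were higher and lys-7 (-0.57) and lys-10 (-0.86) lower, adjusted over the list alone, with a list median of 0.02 (camera adjusted p = 0.78), and without perchlorate replicate 1, 3 were higher and 2 lower. Of 247 C-type lectins clec-52 and clec-227 were higher and clec-17 and clec-258 (-0.93) lower, adjusted over the list alone, with a median of 0.06 (camera adjusted p = 0.642). Of 34 saposin-like and defensin-like peptide genes 4 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.259), and 0 either way without perchlorate replicate 1. Of 22 antimicrobial nlp and cnc peptide genes 2 were higher, nlp-26 (0.83) and cnc-7 (0.63), and 0 lower (camera adjusted p = 0.59), with 3 higher without that array, and of 19 genes of the intracellular pathogen response 0 passed (camera adjusted p = 0.574). Of 37 pals genes 1 was lower, pals-39 (-0.88), and 0 were higher (camera adjusted p = 0.736), and 0 passed without that array. The iron handling list had a median log2 difference of -0.06 over 17 members (camera adjusted p = 0.312). Adjusted over the list alone 4 of its genes were lower and 1 higher, hrg-10 (0.46). The lower ones included the heme transporter genes hrg-1 (-0.56) and hrg-3 (-0.69) and the heme exporter gene mrp-5 (-0.49). Without perchlorate replicate 1, 2 were lower and 0 higher.

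The moulting, cuticle collagen and adult-onset cuticle lists had medians below 0, with camera calls that were lost with an estimated correlation (adjusted p = 0.413, 0.493 and 0.413). A shift that depends on brightness is argued against for the moulting list, whose median of -0.824 lay outside the range of -0.0911 to 0.125 that held the central 95% of 10000 random lists of the same size and brightness, and so is perchlorate replicate 1 as the whole cause, since without it the median was -0.581, outside -0.0946 to 0.109. A candidate explanation is that perchlorate larvae were at another point of the moulting cycle, and that arrays of one group also differed in stage. Across 211 genes of these lists, which are not independent replicates, the difference between a pair of perchlorate arrays correlated with the perchlorate-minus-control difference taken from the remaining perchlorate array at -0.25, -0.63 and -0.51, beside -0.01, -0.14 and -0.13 over all other genes, and the same for control arrays gave 0.19, 0.20 and -0.01, beside 0.15, 0.17 and 0.02. The prediction set beforehand was a correlation beyond 0.2 in size, with the same sign in every comparison of a group. The perchlorate comparisons met it. The control comparisons did not, the smallest being 0.01 in size, so stage stays open. Each difference took the higher replicate number minus the lower, and the reverse order would flip the sign, so a shared sign carries no weight. The median differences of the moulting list were -0.12, -0.13 and -0.03 between control arrays, beside 0.16, 0.65 and 0.53 between perchlorate arrays. The control comparisons could therefore show little. Stage cannot be told apart here from another effect of the exposure, because no array has a stage measured apart from its treatment.

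The chemoreceptor, F-box and mitochondrial ribosomal protein lists had medians above 0, with camera calls that were lost with an estimated correlation (adjusted p = 0.493, 0.682 and 0.493). For the mitochondrial list, the median of 0.189 lay outside the brightness-matched range of -0.0617 to 0.0786, which argues against a brightness-dependent shift, and a biological change remains a hypothesis. For chemoreceptors the median of 0.11 lay above the matched range of 0.0471 to 0.0725, and for F-box genes 0.101 lay above 0.018 to 0.0813, but both calls ended on quantile normalising again (medians 0.0517 and 0.0678). Since the matched lists themselves lie above 0 for such dim genes, part of these differences may come from the lower end of the scale, which these arrays cannot separate from a change in the animals.

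A larger share of germline RNA in the perchlorate samples might lower the share of X-linked genes among the higher ones, because germline genes are few on the X. The odds ratio of 0.712 went that way, as it did without control replicate 3 (0.575) and without perchlorate replicates 1, 2 and 3 (0.842, 0.782 and 0.774), each with a two-sided exact p under 0.05. It was 0.978 without control replicate 1 and 0.949 without control replicate 2 (exact p = 0.772 and 0.474). Among the lower genes, which the prediction did not cover, the odds ratio was 1.46. It lay between 1.42 and 1.62 on leaving out any array, the direction that a larger germline share would also give. The spermatogenesis list had a median of 0.14 (camera adjusted p = 0.0521) and passed without perchlorate replicate 1 (0.0299, and adjusted p = 0.451 with an estimated correlation), while the list of germline proliferation and meiosis did not pass (0.111, and 0.418 without perchlorate replicate 1), and the oogenesis and eggshell median of 0.04 (0.642) was -0.02 without that array (0.526). The question stays open.

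The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. In each of 3 counts 1 of the 10 splits, the real one, gave a result as large. The real split called 2 probe sets and the highest other 0. It had 4291 probe sets at an unadjusted limma p under 0.05 and the highest other 1281. It passed 20 lists and the highest other 16, with control replicates 1 and 3 and perchlorate replicate 2 against the rest. The other splits, which mix the 2 groups, passed 6, 9, 6, 0, 16, 7, 8, 7 and 0 lists, so lists often passed in mixed splits too. Each mixed split still sets more control arrays on one side and more perchlorate arrays on the other. It keeps part of any difference between the groups, so these counts cannot show how often lists pass without one.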
